A study of Mus musculus with 4 samples.

How the data were processed

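Total RNA from 4 groups of mouse neurosphere cells, 1 sample per group, was amplified, biotin-labelled with a whole-transcript kit and hybridised to Affymetrix GeneChip arrays, per the labels' protocols. The values the authors deposited are intensity per probe set on a linear scale, 1 column per array, all above 0 and with medians close together on the 4 arrays. Affymetrix Expression Console was used to make them, per the submitters' processing notes. Its version, the summarisation and normalization method and the genome build are not given in the sources used here, so no coordinates are reported. A common normalization across arrays can hide a shift shared by most genes, and signal from unbound or cross-bound probes compresses differences of dim genes. The number of arrays, not a count depth, limits the precision.

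Groups were taken from the sample labels, which name the virus and the time without FGF. The series design states that part of the infected cells was collected at once and the rest after culture without FGF, which was read as a pair of arrays for each virus; the labels do not say whether EGF was kept after withdrawal. Neither the number of cultures infected per virus nor that behind each array is given, so the virus comparison has 1 independent sample per arm. As a check of the pairing, the difference between the viruses was compared between the FGF conditions, and had r = 0.0914 across 10291 genes. The 2 arrays of a virus thus deviated together only weakly, and the pairing rests on the design text and not on this check.

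Probe sets were named from the platform annotation supplied with the series. Of 28944 probe sets, 21789 had 1 gene symbol, 1621 had several and 5534 had none here, and only the first kind was used. Values were transformed as log2(intensity + 1) and probe sets of a gene were averaged, giving 19938 genes. A gene was kept if it reached the median of the named probe sets on at least 1 of the 4 arrays, which left 10291. A gene near that level could thus enter through the array or condition in which it was high. Fold changes are on this log2 scale with its pseudocount of 1 and understate changes of dim genes. No further scaling was applied.

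FGF withdrawal was tested with limma 3.58.1 in R 4.3.3, with the infected culture as an additive term and withdrawal as the tested term, two-sided, with empirical Bayes variances (prior degrees of freedom 6.59, residual degrees of freedom 1) and Benjamini-Hochberg adjustment over the 10291 genes, at 0.05. Because the residual holds the interaction of virus and withdrawal, that interaction and the virus were not tested and are given as differences of log2 values. Genes past 2-fold were counted in each direction. The procedure was tested on simulated data with 200 changed genes among 10291, 50 for each fold. It called 34% of genes changed 1.2-fold and 100% of those changed 1.5-fold, 2-fold or 4-fold, and 15 of 10091 unchanged genes. The simulated noise was independent between genes and held no trend with level, and far more genes (5289) were called in the data. These rates therefore need not hold for the data.

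Before the data were examined, 24 gene lists were fixed, with 488 genes, of which 459 had a probe set of their own and 332 were analysed. For each list the median was placed among 10000 random lists of the same size drawn from genes matched on mean expression in 20 bins. This percentile describes the arrays and tests no group. Counts adjusted over the list alone repeat the adjustment within the list. The genes to be named were also fixed beforehand: Hmga2 and related genes of the HMGA and IMP families always, the 10 highest and 10 lowest by the smaller of the 2 virus differences with the same sign, the 10 that rose and the 10 that fell most on withdrawal, the 5 highest and 5 lowest differences of response, and up to 4 members of each list with at least 5 analysed members for each comparison. Predicted genes without a proper name and olfactory receptor genes were passed over in these ranks. Members outside this rule that made up a count of 5 or fewer in a list (such as Vgf, Myc, Ier3, Slbp, Btg2, Cst3, Pmvk and the ependymal genes), Frmd6, Olfr767 and the genes of the symbol families were named after their values were seen.

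Alternatives were quantile normalization, centring, removal of the trend with level by loess, other filters, the brightest probe set per gene, pseudocounts of 10 and 0.1, other variance priors, no culture term, a threshold of 0.1, a size threshold of 1.5-fold and each culture alone. A test against a 1.5-fold change and a count of called genes that changed at least 2-fold in both cultures were added after the data were seen. Figures were drawn with matplotlib 3.10.9.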

Results

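Gene expression was measured on 4 whole-transcript arrays in mouse neural precursor cells that carried a control retrovirus or a retrovirus expressing HMGA2, a chromatin-binding protein of the high mobility group AT-hook family. Neuroepithelial cells were taken from the neocortex of Jcl:ICR embryos at embryonic day 11.5 and grown for 9 days as neurospheres, floating clusters of precursor cells, with fibroblast growth factor 2 (FGF2) and epidermal growth factor (EGF). The cells were then infected and kept in both growth factors for 3 days. Part of the infected cells was collected at once (0 h) and the rest after 12 h without FGF. The design therefore held 4 groups with 1 array each. The cells infected with 1 virus are called a culture here; how many dishes or infections they came from is not given in the sources used here. Median intensity was 156 to 161 over the 28944 probe sets of each array, and the highest intensity lay between 22055 and 23795. Of 19938 genes with a probe set of their own, 10291 passed the level filter.

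The product carried by the virus was examined first. Hmga2 (probe set 10372796) read 374.1 in control virus cells and 420.0 in HMGA2 virus cells with FGF, a difference of 0.17 on the log2 scale (1.12-fold). After withdrawal the values were 336.3 and 486.7, a difference of 0.53 (1.45-fold). Among the 500 genes nearest to it in expression level, the Hmga2 difference lay at percentile 94.2 with FGF and 100 after withdrawal. Where on the transcript this probe set reads, and whether that part was in the viral insert, is not given in the sources used here, so these values are no measure of the amount of HMGA2 made. Igf2bp3, an RNA-binding protein of the IMP family, read 1069 and 981.4 with FGF and 934.2 and 885.6 after withdrawal, in control and HMGA2 virus cells. Its relative Igf2bp1 lay below the level filter, with values from 56.2 to 61.8 on the 4 arrays. Hmga1 and Igf2bp2, also fixed to be named, had no probe set of their own and could not be read.

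The first tested comparison asked which genes changed within 12 h of FGF withdrawal, with the 2 arrays of each virus as a pair. Immediate early genes, genes that feed back on FGF and ERK signalling, and genes of cell division fell. More neurogenic, interneuron and oligodendrocyte genes rose than fell. The same held over all 10291 genes, of which 34.2% rose and 17.2% fell. Of 28 analysed FGF and ERK feedback and immediate early genes, 22 fell, 3 rose and 3 did not pass the test. Fosb, a subunit of the AP-1 transcription factor, fell 16.7-fold, from 2983 and 2706 in the control and HMGA2 cultures to 177.0 and 162.4 (log2 change -4.06 ± 0.06, adjusted p = 5.08e-08; here and below ± gives the standard error moderated by limma, which rests mostly on the spread pooled over all genes). Fos changed by -3.67 ± 0.07, the zinc finger factor Egr1 by -2.56 ± 0.12, and Dusp6, a phosphatase that inactivates ERK, by -1.14 ± 0.12. Adjusted over the list alone, the counts were also 22 and 3. The 3 members that rose were Fosl1 (0.91), Vgf (1.0) and Myc (0.46). Fosl1 and Vgf passed the level filter only on arrays after withdrawal, so their rises favoured their entry. Several genes outside the list fell with them: the orphan nuclear receptors Nr4a1 (14.3-fold) and Nr4a3 (5.47-fold), the mRNA decay factor Zfp36 (12.2-fold), the MAP kinase phosphatase Dusp1 (7.62-fold), the matricellular gene Ccn1 (6.23-fold) and the metalloprotease Adamts1 (5.20-fold).

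Genes of the cell division cycle fell as a group. Of 25 analysed G2 and M phase genes, 25 fell, also when adjusted over the list alone, with a median log2 change of -1.60. Ccnb2, a mitotic cyclin, changed by -2.18 ± 0.06, the kinetochore gene Cenpf by -2.02 ± 0.09, the proliferation marker Mki67 by -2.0 ± 0.09 and the mitotic kinase Plk1 by -2.0 ± 0.09. Mki67 read 1996 and 1693 with FGF and 436.0 and 484.1 after withdrawal, in the control and HMGA2 cultures. Among 21 S phase genes 18 fell, 1 rose and 2 did not pass, and 19 fell when adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, changed by -0.89 ± 0.07, the repressor E2f8 by -0.83 ± 0.07 and the replicative helicase subunit Mcm3 by -0.78 ± 0.07. Slbp, which binds histone mRNA, rose by 0.39. The list of linker histone and other HMG genes had 11 analysed members, all HMG or Cbx genes and none a linker histone; 5 fell, 2 rose and 4 did not pass, with 6 falling when adjusted over the list alone. Hmgb2 fell 2.17-fold, Hmgn5, Hmg20b, Hmgn3 and Hmgb3 also fell, and Hmgn1 and Hmgb1 rose. After quantile normalization 5 of the 11 fell and 0 rose.

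Among genes of neuron production more rose than fell, with list medians at percentiles 99.9 (proneural and intermediate progenitor genes), 99.4 (neuronal genes) and 100 (GABAergic interneuron genes) of matched random lists. Of 13 proneural and intermediate progenitor genes 9 rose, 1 fell and 3 did not pass, with counts of 9 and 1 adjusted over the list alone. Nhlh1 rose by 0.93 ± 0.06, Insm1 by 0.88 ± 0.06, the proneural factor Neurog2 by 0.82 ± 0.08 and Eomes, a marker of intermediate progenitors, by 0.74 ± 0.06. Btg2 fell by 0.73. Among 18 neuronal genes 11 rose and 7 did not pass, and 11 rose when adjusted over the list alone, including the neurofilament gene Ina (0.83 ± 0.07), the synaptic vesicle gene Syt1 (0.82 ± 0.06) and Rbfox3 (0.71 ± 0.06). All 7 analysed GABAergic interneuron genes rose, 7 also when adjusted over the list alone. The list had 17 members with a probe set, and those not analysed lay below the level filter. Sp8, like Eomes and Nhlh1 above, passed that filter only on the arrays after withdrawal, so its rise favoured its entry. Dlx1, a homeobox gene of interneuron precursors, rose 2.54-fold, from 246.0 and 318.5 to 702.6 and 722.5. Sp8 rose by 0.81 ± 0.06 and Gad1, which makes GABA, by 0.58 ± 0.06.

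Glial and precursor genes divided. Of 16 oligodendrocyte lineage genes 12 rose and 4 did not pass, with 12 also adjusted over the list alone. Their median change lay at percentile 99.97 of matched random lists, and after removal of the trend with level 9 rose and 1 fell. The largest changes were those of Ugt8a (0.55 ± 0.07), Gpr17 (0.54 ± 0.06) and Bcas1 (0.45 ± 0.06). Of 18 astrocytic genes 14 fell, 2 rose and 2 did not pass, with 15 falling when adjusted over the list alone. The bicarbonate transporter gene Slc4a4 changed by -1.47 ± 0.06, Acsbg1 by -1.24 ± 0.06 and Id3 by -0.95 ± 0.06, while Clu rose by 0.79 ± 0.06 and Cst3 by 0.27. Gfap, the astrocyte filament gene, fell by 0.21. Among 15 Notch pathway genes 6 fell, 1 rose and 8 did not pass, with the same numbers adjusted over the list alone. Hes1, a transcriptional target of Notch, changed by -1.24 ± 0.09, Lfng by -0.96 ± 0.07 and Notch3 by -0.76 ± 0.06, while Rbpj rose by 0.22. Of 19 neural precursor and radial glial genes 7 fell, 2 rose and 10 did not pass, and adjusted over the list alone 8 fell and 3 rose. The matrix gene Tnc changed by -1.14 ± 0.07, Hopx by -0.62 ± 0.11 and Lhx2 by -0.45 ± 0.06, and the 2 that rose were Pou3f2 and Msi1.

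Metabolic, stress and signalling lists are given against the share of all 10291 genes, of which 34.2% rose and 17.2% fell. Of 20 cholesterol synthesis genes 16 fell, 1 rose and 3 did not pass, and 18 fell when adjusted over the list alone. Insig1, a sterol-regulated inhibitor of the pathway, fell 2.75-fold and Dhcr7, the last enzyme of the pathway, 1.69-fold, while Pmvk rose by 0.18. Of 20 integrated stress response and unfolded protein genes 12 rose, 5 fell and 3 did not pass, with 12 and 5 adjusted over the list alone. Asns, which makes asparagine, rose by 1.39 ± 0.08 and Chac1 by 1.33 ± 0.10, and the cystine transporter gene Slc7a11 changed by -1.24 ± 0.14. Atf3, Hspa5, Sdf2l1 and Psat1 also fell. Among 15 p53 targets 8 rose, 4 fell and 3 did not pass, with 10 rising when adjusted over the list alone. Fas rose by 0.80 ± 0.10 and Phlda3 by 0.74 ± 0.06. Gtse1, a member with a role in mitosis, changed by -0.70 ± 0.06, and Perp, Plk2 and Plk3 fell too. Of 16 growth factor repressed FOXO targets 7 rose, 2 fell and 7 did not pass, with 7 and 2 adjusted over the list alone. Txnip, an inhibitor of thioredoxin, rose 8.48-fold, Irs2 fell 1.58-fold and Btg1 fell by 0.25. Of 19 growth factor receptors and ligands 6 rose, 2 fell and 11 did not pass, with 6 and 2 adjusted over the list alone; the EGF receptor ligand Hbegf rose 2.77-fold, and Fgf1 and Lifr fell.

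Among the remaining groups, 8 of 12 imprinted growth genes rose and 2 fell, with 8 and 2 adjusted over the list alone, and Peg10 rose 2.07-fold and Plagl1 1.65-fold, while Igf2r and Peg3 fell. Of 20 Polycomb and chromatin regulators 10 rose and 3 fell, with 11 rising when adjusted over the list alone; Pcgf2 rose by 0.61 ± 0.07, and Dnmt1, Cbx7 and Cbx8 fell. Of 6 extracellular matrix and mesenchymal genes 3 rose and 1 fell, as they did adjusted over the list alone, with Acta2, the smooth muscle actin, rising by 2.40 ± 0.06, Timp1 and Fn1 also rising and Thy1 falling. The list of HMGA, IMP and LIN28 genes and genes connected with them had 5 analysed members, none of them a LIN28 gene. Its connected genes Mycn and Plagl2 rose by 0.77 ± 0.08 and 0.59 ± 0.07, Igf2bp3 fell by 0.17, and Hmga2 and Cdkn2b did not pass, with 2 rising and 1 falling also when adjusted over the list alone. Of 3 ependymal and choroid plexus genes 2 rose, and 3 rose adjusted over the list alone; they were Foxj1 (0.51), Rfx2 (0.17) and Rfx3 (0.16). None of 5 interferon response genes passed the limma test over all genes or adjusted over the list alone, while 2 of them were lower at an unadjusted p under 0.05. After quantile normalization 2 of the 5 fell, so this result depended on the scaling. Ifi203 and Ifi202b, interferon-inducible genes outside that list, rose by 3.72 ± 0.07 and 2.35 ± 0.18; they belong to a cluster of closely similar genes, and their probe sets could not be separated from such relatives here. The endothelial and mural list and the microglial and immune list had 1 analysed member each and were not described as groups. Other large rises were those of the caveolar gene Cav1 (3.33 ± 0.06), the receptor gene Gpr50 (3.12 ± 0.20), the secretory granule gene Scg2 (2.25 ± 0.19), Ripply1 (2.05 ± 0.10), the hyaluronan-degrading Cemip (2.0 ± 0.07) and Ptgs2, the inducible cyclooxygenase (2.0 ± 0.07). Gpr50, Scg2, Ripply1 and Cemip passed the level filter only on arrays after withdrawal, as did Acta2, Mycn, Ifi203 and Ifi202b. The rises of these genes thus favoured their entry.

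Over all 10291 genes, 3522 rose and 1767 fell (limma, Benjamini-Hochberg adjusted p under 0.05). Without the filter on dim genes, over 19938 genes, 1408 rose and 1310 fell. Most changes were small, 55 of the genes that rose and 169 of those that fell being at least 2-fold in the mean. Changes of at least 2-fold in both cultures numbered 42 upward and 148 downward, against 0.3 and 2.97 for independent lists. Across genes, which are not independent replicates, the responses of the 2 cultures had r = 0.916 and rho = 0.856. The median change of all genes was 0.08, and after removal of the trend with expression level 2457 genes rose and 2371 fell, a share of 50.9% rising against 66.6% for the deposited values. The test rests on 2 pairs of arrays with 1 residual degree of freedom, so the p-values measure only the spread between these arrays, which may be technical. The cells without FGF were also collected 12 h later, and time in culture cannot be separated from withdrawal.

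**Figure D1:**
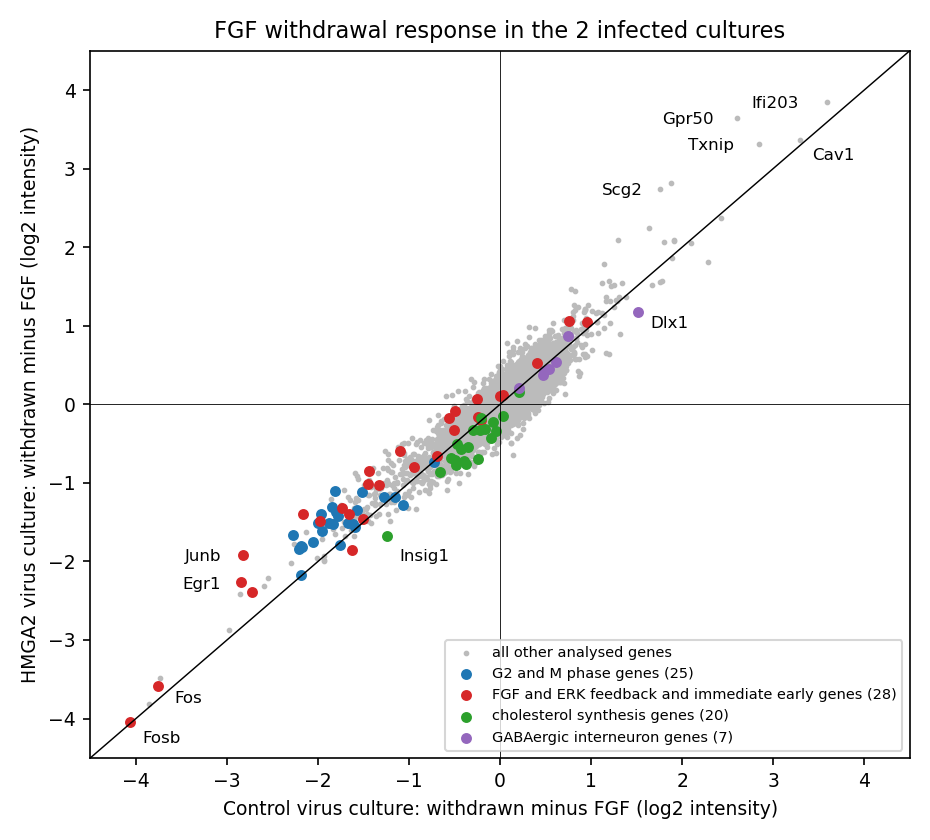
Log2 change of intensity on FGF withdrawal for each of 10291 genes in the control virus culture (horizontal) and the HMGA2 virus culture (vertical), with 1 array per condition and culture. The line marks equal change; 27 of 28 FGF and ERK genes (red) lie above it and 19 of 20 cholesterol synthesis genes (green) lie below it.

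The second question was what the HMGA2 virus altered in cells kept in FGF. With 1 array per virus there was no replicate check and no test, and the values describe these arrays. Genes of cell division were lower with the HMGA2 virus: 23 of 25 G2 and M phase genes, with a median difference of -0.26, and 17 of 21 S phase genes, with a median of -0.14. Aurkb, a mitotic kinase, read 942.1 with the control virus and 658.9 with the HMGA2 virus (-0.52), Nek2 334.3 and 232.3 (-0.52), Rrm2 585.7 and 423.5 (-0.47) and Mcm3 232.9 and 175.6 (-0.41). Mcm3 passed the level filter only on the control array with FGF. Both medians lay at percentile 0 among 10000 random lists of the same size matched on expression level. Of 15 p53 targets 13 were lower (median -0.13, percentile 0.01), and of 28 FGF and ERK genes 22 were lower (median -0.10, percentile 0), Arc by -0.37. Of 20 cholesterol synthesis genes 17 were lower as well (median -0.06, percentile 0.46).

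Neurogenic and precursor lists were not displaced with the HMGA2 virus in FGF. Higher were 9 of 13 proneural and intermediate progenitor genes (median 0.03, percentile 77.2), 11 of 18 neuronal genes (median 0.02, percentile 70.6), 6 of 7 GABAergic interneuron genes (median 0.07, percentile 94.1) and 10 of 19 neural precursor and radial glial genes (median 0.01, percentile 53.4). Among the members furthest above 0, Eomes read 120.1 and 151.0 in control and HMGA2 virus cells (0.33) and Neurog2 257.4 and 294.5 (0.19). Dlx1 read 246.0 and 318.5 (0.37), Hopx 140.6 and 191.3 (0.44) and the growth cone gene Gap43 497.5 and 588.7 (0.24). Hopx passed the level filter only on the HMGA2 array with FGF. Across the 10291 genes the differences ran from -0.60 to 0.51, with an SD of 0.106. No gene was 2-fold higher or lower, and at 1.5-fold 1 gene was lower, Frmd6 (-0.60), and 0 were higher.

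After FGF withdrawal the lists furthest from 0 were those of cholesterol synthesis and of FGF and ERK signalling. All 20 cholesterol synthesis genes were lower with the HMGA2 virus, with a median of -0.30 at percentile 0. Fdps, the farnesyl diphosphate synthase, read 764.9 and 535.7 in control and HMGA2 virus cells (-0.51), Insig1 1126 and 808.4 (-0.48) and the sterol dehydrogenase Nsdhl 1164 and 842.8 (-0.46). FGF and ERK genes were instead higher in 22 of 28 cases (median 0.17, percentile 100). Junb read 114.8 and 191.7 (0.73), Egr2 406.8 and 607.9 (0.58), Fosl1 162.1 and 227.8 (0.49) and Egr1 585.8 and 816.4 (0.48). Of 20 integrated stress response and unfolded protein genes 16 were higher (median 0.10, percentile 100), Slc7a11 by 0.60, and 14 of 19 growth factor receptors and ligands were higher (median 0.09, percentile 99.9), Hbegf by 0.51. Of 15 Notch pathway genes 9 were lower (median -0.14, percentile 0). The median of the G2 and M phase genes was 0.04 (percentile 91.2) and that of the S phase genes 0.01 (percentile 68.6). Neurog2 read 412.8 and 574.2 (0.48) and Neurod1 311.9 and 391.0 (0.33), while Mfap4 (-0.36) and Gadd45g (-0.33) differed the other way and the proneural list had a median of 0.01. No gene was 2-fold higher or lower. At 1.5-fold 4 were higher, namely Scg2 (0.82), Junb (0.73), Ifi202b (0.73) and Slc7a11 (0.60), and 1 was lower, Olfr767 (-0.61). Fosl1 and Ifi202b passed the level filter only on the HMGA2 array after withdrawal.

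**Figure D2:**
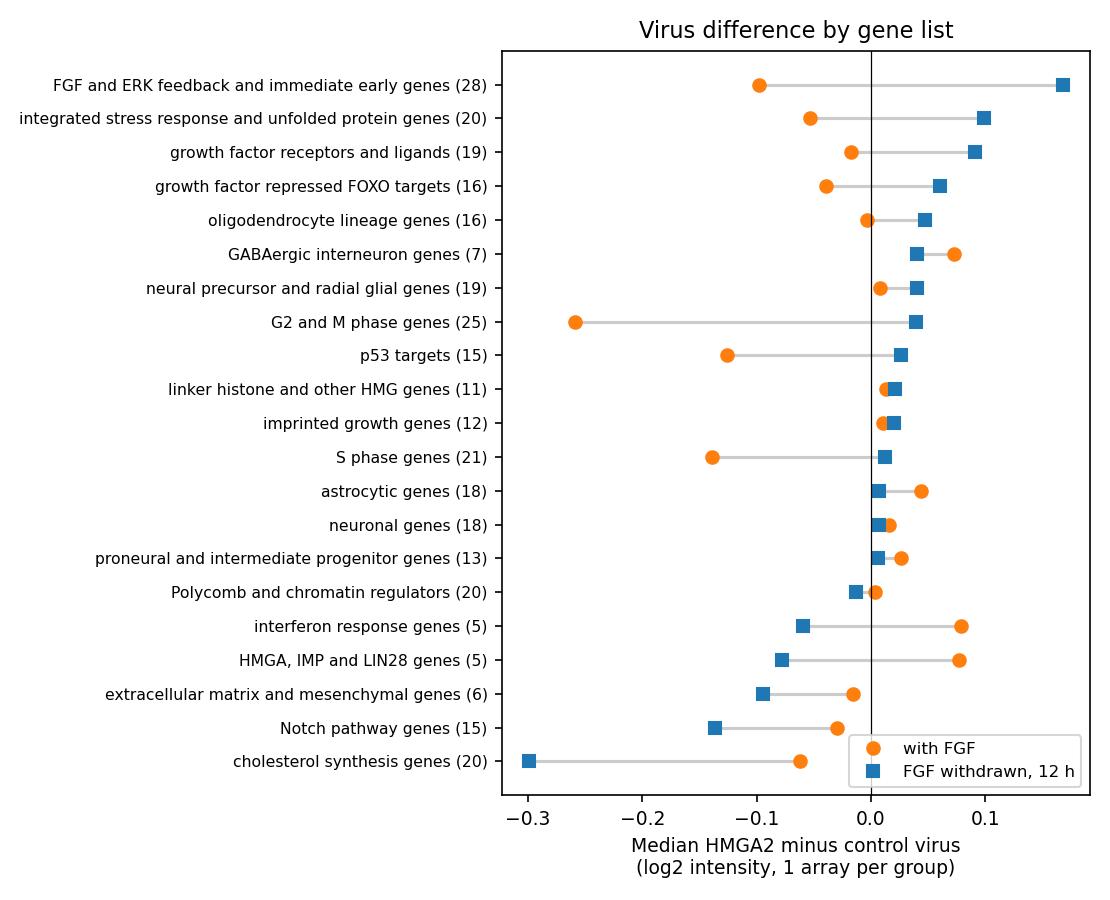
Median log2 difference between HMGA2 and control virus cells over the analysed members of each gene list (number in brackets), with FGF (orange circles) and after 12 h without FGF (blue squares), 1 array per group. G2 and M phase genes lie at -0.26 with FGF and 0.04 without, cholesterol synthesis genes at -0.06 and -0.30, and FGF and ERK genes at -0.10 and 0.17.

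Genes with a difference of the same sign in both FGF conditions were ranked by the smaller of their 2 differences. Highest were Cbln2, a synaptic organiser (0.51 with FGF and 0.34 after withdrawal), and the phosphodiesterase Pde1a (0.30 and 0.33). Both passed the level filter only on the HMGA2 array after withdrawal, so a high value there favoured their entry. Next came Phgdh, the first enzyme of serine synthesis (0.39 and 0.30), Dbndd1 (0.37 and 0.28) and the oligodendrocyte enzyme Enpp6 (0.30 and 0.28). Trmt10c, Ifi203, Rny1, Cav1 and the purine receptor P2ry1 (0.25 and 0.35) completed the first 10. Lowest were Troap (-0.48 and -0.35), the small heat shock protein gene Hspb8 (-0.31 and -0.50) and the nicotinic receptor gene Chrna4 (-0.30 and -0.38). In order of rank, Haus8 (-0.29 and -0.36), Gtse1 (-0.28 and -0.32), Aurka (-0.38 and -0.28) and Kif18b (-0.34 and -0.28) followed. Niban3 (-0.27 and -0.35), Mybl2 (-0.26 and -0.27) and Topbp1 (-0.26 and -0.32) were the rest of these 10. Hspb8 and Haus8 passed the level filter only on a control virus array. The fixed list of G2 and M phase genes had a median of -0.26 with FGF and 0.04 after withdrawal. No gene was 2-fold or 1.5-fold apart in the same direction in both conditions. Over all genes the virus differences of the 2 conditions had r = 0.0914 and rho = 0.104 across genes, and 53.9% of genes had the same sign. No source names more than 1 culture per virus, so a difference between the cultures cannot be told from an effect of HMGA2.

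The last comparison set the response to FGF withdrawal in the HMGA2 culture against that in the control culture, as a difference of 2 differences without a test. FGF and ERK genes had a median response of -0.82 in the HMGA2 culture and -1.21 in the control culture, and the difference was above 0 for 27 of 28 genes (median 0.28, percentile 100). Of the 22 members that fell, 21 fell by less in the HMGA2 culture and Ier3 by more, while the 3 that rose (Fosl1, Vgf and Myc) rose by more. Junb had a response of -2.82 in the control culture and -1.92 in the HMGA2 culture, Egr2 -2.16 and -1.40, Dusp6 -1.44 and -0.85, and Egr1 -2.85 and -2.27. Fosb had nearly equal responses of -4.07 and -4.05. The difference was also above 0 for 21 of 25 G2 and M phase genes (median 0.35) and 17 of 21 S phase genes (median 0.20). For these lists it came mostly from lower values with FGF. Their median virus differences were -0.26 and -0.14 with FGF, and 0.04 and 0.01 after withdrawal. For cholesterol synthesis genes the difference of responses was below 0 in 19 of 20 cases (median -0.19). For Nek2 the responses were -1.82 and -1.10, and for Fdps -0.24 and -0.69. Of the 169 genes that fell at least 2-fold in the mean, 137 had the smaller response in the HMGA2 culture, as did 16 of the 55 that rose at least 2-fold.

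Among single genes, the response of Gpr50 was 2.60 in the control culture and 3.65 in the HMGA2 culture, Scg2 1.76 and 2.74, Ifi202b 1.88 and 2.82, and the receptor kinase gene Met 1.30 and 2.09. With FGF, Scg2 read 111.8 and 100.2, Ifi202b 43.7 and 37.8 and Met 65.9 and 55.9, so these responses, like that of Gpr50, start from dim values whose background was not measured. Ifi202b and Met passed the level filter only on the HMGA2 array after withdrawal. At the other end stood Lce1h (0.19 and -0.43), Gabarapl2 (0.12 and -0.49), Htr3a (0.71 and 0.13), Krt8 (-0.04 and -0.62) and Ndufb3 (0.25 and -0.31). Lce1h passed the filter only on the control array after withdrawal. The value of Gabarapl2 averages 2 probe sets, and with the probe set with the highest mean alone its difference of responses was -0.09. Gpr50, at 44.0 to 66.2 with FGF, was the 1 gene with a 2-fold difference of responses; with a pseudocount of 10 there were 0, after removal of the trend with level 3 higher, and without the filter on dim genes 12 higher and 15 lower. At 1.5-fold 30 genes had a higher response in the HMGA2 culture and 5 a lower one. The value for each of these genes rests on 4 single arrays.

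**Figure D3:**
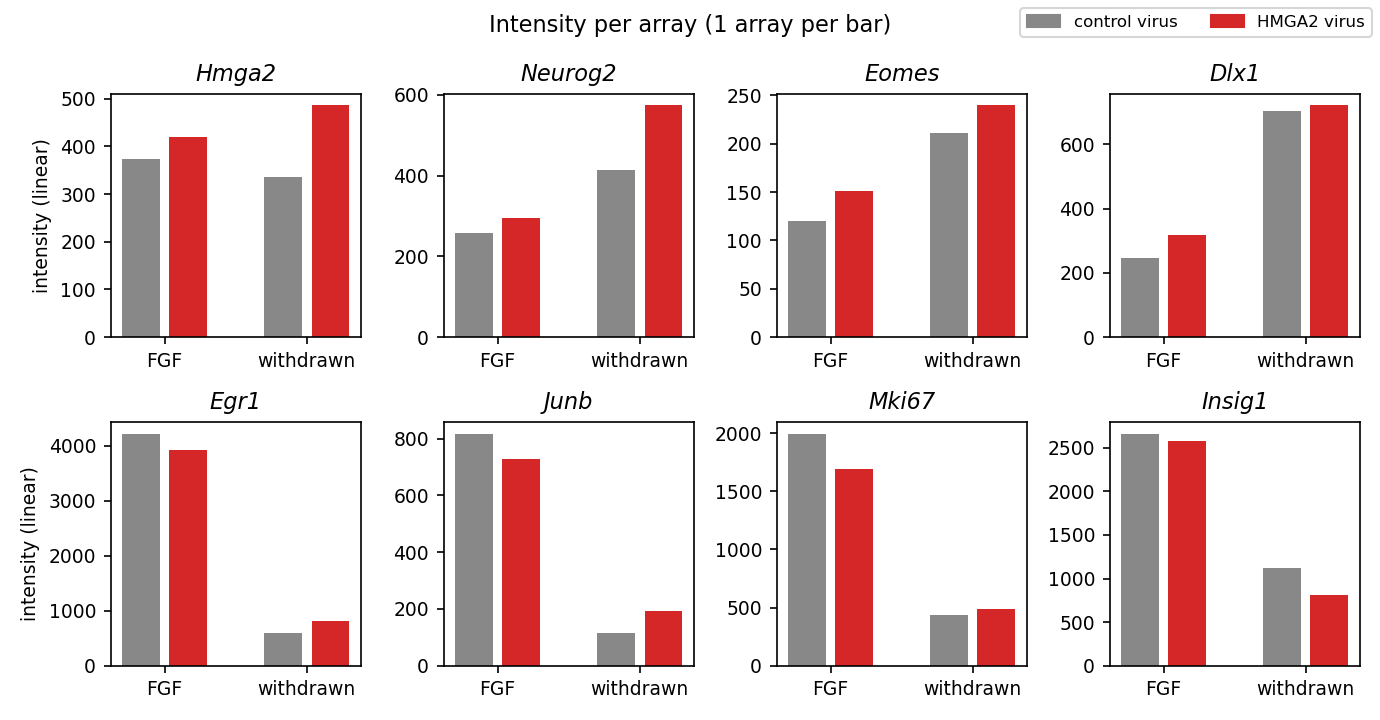
Linear intensity of 8 genes on each of the 4 arrays, with control virus cells in grey and HMGA2 virus cells in red, with FGF (left pair) and after 12 h without FGF (right pair), 1 array per bar and no error bars. Hmga2 reads 374.1 and 420.0 with FGF and 336.3 and 486.7 without, and Insig1 2663, 2583, 1126 and 808.4 in the same order.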

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

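The tests of explanations in this part were chosen after the results were seen; removal of the trend with level was also among the alternatives fixed beforehand. For 7 gene lists with a median outside the central 95% of matched random lists in at least 1 condition, the virus difference had opposite signs, below 0 with FGF and above 0 after withdrawal; these differences between the conditions were not tested. The median moved up by 0.266 for FGF and ERK feedback and immediate early genes, 0.298 for G2 and M phase genes, 0.151 for S phase genes, 0.152 for p53 targets, 0.152 for integrated stress response and unfolded protein genes, 0.108 for growth factor receptors and ligands and 0.099 for growth factor repressed FOXO targets. Single genes with virus differences of opposite sign, also untested, had these differences of response (HMGA2 culture minus control culture): Gpr50 1.05, Scg2 0.98, Ifi202b 0.94, Junb 0.90, Met 0.79, Lce1h -0.62, Gabarapl2 -0.61, Htr3a -0.58, Krt8 -0.57 and Ndufb3 -0.56. With the brightest probe set of Gabarapl2 alone, its virus difference after withdrawal was 0.0352 and no longer of opposite sign. Among the 7155 probe sets without a single gene symbol, which entered no comparison, 4 were at least 2-fold higher after withdrawal in both cultures and 29 at least 2-fold lower.

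In cells kept in FGF, 23 of 25 G2 and M phase genes were lower with the HMGA2 virus. A trend of the difference with probe level does not account for it, since the list median was -0.265 after the trend was removed, at percentile 0 among matched random lists. A culture already partly in the state of FGF withdrawal would lower every gene that falls on withdrawal. Other genes with the same response in the control culture had a median of -0.106. That response and the virus difference share the control array with FGF, and noise on that array would lower both. The median of -0.106 therefore cannot tell whether such a shift was present. The list lay below these genes, at percentile 0.305 among random lists matched on that response. A shift equal for all of them would thus not make up the whole difference. A smaller share of dividing cells with the HMGA2 virus is an untested hypothesis, for which dividing cells could be counted in several cultures per virus. It cannot be told apart here from a difference between the 2 infected cultures, with 1 array per virus and condition.

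On withdrawal, 21 of the 22 FGF and ERK genes that fell did so by less in the HMGA2 culture. A single smaller scale for rises and falls alike does not account for it. Over all genes the responses had SDs of 0.371 and 0.368 in the control and HMGA2 cultures. Of the genes past the test 47.8% had the smaller response in the HMGA2 culture, as did 16 of the 55 that rose at least 2-fold. These values pool rises with falls or cover rises alone, so they cannot exclude a smaller scale of falls alone. Genes that fell at least 2-fold did so by less in 137 of 169 cases, but after the slope across genes (0.907) was removed the FGF and ERK genes kept a median residual of 0.16, at percentile 99.6 among random lists matched on the control response. The floor of the arrays would draw the 2 cultures together after withdrawal, whereas the 28 list members then had a median virus difference of 0.168 (percentile 100). On these arrays this argues against the floor as the whole cause. The 8 members that were brightest after withdrawal in the control culture, at 526.6 or more, had a median response difference of 0.211. They included Myc, which rose, and Etv1 and Spred1, which did not pass, so that median alone cannot decide on the floor for genes that fell. The others, Jun, Ccnd1, Egr1, Spry2 and Fosl2, fell, with response differences of 0.29, 0.03, 0.58, 0.44 and 0.40. On these arrays their smaller falls did not arise near the floor. The standard errors across members (0.055 and 0.089) treat related genes on the same arrays as independent and measure no spread between cultures. With FGF, 22 of the 28 list members were lower with the HMGA2 virus (median -0.10). Part of the difference of responses thus came from a lower start, and the list median was higher only after withdrawal. Sustained ERK signalling after withdrawal with the HMGA2 virus is a hypothesis that was not tested. Phosphorylated ERK measured in several cultures per virus would decide it. A difference between the cultures, such as how completely FGF was removed, stays open.

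After withdrawal, 20 of 20 cholesterol synthesis genes were lower with the HMGA2 virus. Removal of the trend with level left a list median of -0.292, at percentile 0 among matched random lists. Other genes with the same withdrawal response in the control culture had a median virus difference of 0. That response and the virus difference share the control array after withdrawal with opposite sign, so noise on that array could hide a general lowering. The median of 0 therefore cannot exclude a general lowering of genes that fall on withdrawal. The cholesterol list lay at percentile 0 of random lists matched on that response, and was thus lower than genes with a like response. A lower activity of sterol-regulated transcription with the HMGA2 virus may be followed up as an untested hypothesis, by measuring processed SREBP2 in several cultures per virus. A difference in cell density or medium between the 2 cultures stays open too, since each virus had 1 array per condition.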

How the results depend on the processing

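A test against a 1.5-fold change and the count of called genes at least 2-fold changed in both cultures were chosen after the results were seen; all other alternatives were fixed beforehand. Of 686 results, 533 kept their direction, their side of the threshold and about their size under every alternative run. Without a filter on dim genes 1408 genes rose on FGF withdrawal (3522 with it), 1 gene was 2-fold lower with the HMGA2 virus in FGF, 1 was higher and 1 lower after withdrawal, and 12 and 15 genes had a 2-fold higher and lower response in the HMGA2 culture; more, dimmer genes were then tested. With the filter at the 75th percentile, which leaves fewer genes, 2081 rose and 1015 fell, and 2-fold changes numbered 26 up and 107 down in the control culture and 30 and 98 in the HMGA2 culture. At 1.5-fold the virus counts were 1 lower with FGF and 4 higher and 1 lower after withdrawal, the withdrawal counts 280 and 444 in the control and 313 and 441 in the HMGA2 culture, and the differences of response 30 and 5. Genes at least 2-fold the same way in both cultures numbered 42 and 148, also when the limma call was required, and 73 rose and 209 fell in the test against 1.5-fold. The 1 gene with a 2-fold higher response became 3 after removal of the trend with level and 0 with a pseudocount of 10; the cause was not tested. The median response difference of imprinted growth genes turned to -0.0385 with the stricter filter, and the virus difference of Gabarapl2 after withdrawal to 0.0352 with its brightest probe set; the cause was not tested. Leaving out the replicate block, the culture term, gave 3356 genes rising and 1676 falling. Neither count moved by over 1.5 times. Named genes lost their call in 47 combinations of gene and alternative, mostly without the filter, and Rfx3 gained one with the stricter filter. Calls within lists moved with the scaling too. After removal of the trend with level, 2 of 4 interferon response genes and 6 of 19 growth factor receptors and ligands fell. Of 11 HMG and Cbx genes and of 20 cholesterol synthesis genes 0 rose, and of 20 Polycomb and chromatin regulators 6 rose. The deposited values hold no measure of background, so the limit that signal over background sets for dim genes was not measured.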

Other observations

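Families of genes that share a symbol stem were examined after the data were seen, with two-sided Fisher's exact tests of the genes that rose and of those that fell on FGF withdrawal (112 families, 224 tests, Benjamini-Hochberg adjusted). Genes of a family are not independent, so these p-values describe the 10291 genes and not further samples. Zinc finger genes of the Zfp family rose broadly, 149 of 256 rising and 9 falling, with a median change of 0.23 (adjusted p = 5.97e-13 for the share that rose and 1.32e-09 for the share that fell). Zfp975 rose by 0.87 ± 0.07 (standard error moderated by limma) and Zfp553 by 0.81 ± 0.06, whereas Zfp36, an mRNA decay factor and not a DNA-binding member, was among the genes that fell most. Zbtb transcription factor genes rose in 22 of 35 cases (adjusted p = 0.016). After removal of the trend with level, 124 Zfp genes rose and 17 fell, and 20 Zbtb genes rose.

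All 16 analysed genes of the protocadherin beta cluster (Pcdhb), neuronal cell surface adhesion genes, rose on withdrawal, with a median of 0.44 (adjusted p = 2.59e-06), and 16 rose under each of the 3 other scalings. These genes lie in 1 cluster and are closely similar in sequence, so their probe sets are not independent readings. RNA polymerase subunit genes (Polr) rose in 18 of 25 cases (adjusted p = 0.00698), and in 9 after removal of the trend with level. Of 26 kinesin motor genes (Kif), several of which act in mitosis, 12 fell and 7 rose (adjusted p = 0.016 for the share that fell). Cytochrome P450 genes (Cyp) fell in 7 of 12 cases (adjusted p = 0.0345). Solute carrier genes (Slc) fell in 48 of 174 cases, more than other genes (adjusted p = 0.016), and rose in 35, fewer than other genes (adjusted p = 0.00277). Further families passed 0.05 in these Fisher's exact tests. Of 12 Prpf genes 10 rose (adjusted p = 0.0171), but 3 after removal of the trend with level. At an adjusted p of 0.0425 each, 6 of 10 Cdh genes fell, 0 of 16 Abhd genes rose, and 1 of 46 Eif and 0 of 35 Vps genes fell. After removal of the trend 7 Vps genes fell.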
